A study of Mus musculus with 4 samples.

How the data were processed

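Draining lymph node tissue of mouse was profiled on a Visium slide, which captures RNA on an array of barcoded spots under a tissue section. The 4 sections share 1 sample ID stem in the labels, and the number of animals is not given in the sources used here. Per the labels, the mice had been immunized 14 days and gavaged 3 days before collection, the node was frozen, and 4 sections of 10 µm, lying 50 µm apart in depth, were placed on the slide, permeabilized for 18 min and amplified over 16 PCR cycles. The submitters' processing notes name Space Ranger 1.3.1, Seurat 4.2.1 and the mouse build mm10. The parameters of these steps, the spot filter, the clustering settings, the rule by which regions were named and the gene lists behind the scores are not given in the sources used here.

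A deposited table with 1 line per spot was the source of all measurements. The total count per spot and the number of genes with a count are raw counts, and the deposited values were used without normalization. The deposited table also gives the percent of counts from mitochondrial and from ribosomal genes, by its column names. It holds 6 scores per spot, which the authors deposited under the names Mo_GC_vs_Mem, pc_markers, Mo_Nr4a1_SC, Mo_Inmt_SC, Mo_Nr4a1Inmt_SC and Mo_CD34_SC. The score pc_markers is read here as a plasma cell marker score and Mo_GC_vs_Mem as a germinal centre score, from their names and the subject of the series, and the other 4 keep their names because the files do not spell them out. Such scores have no true zero, so differences between regions are given and no ratios. The authors' 8 region names were used as deposited, with DZ for the germinal centre dark zone and LZ for the light zone. Cluster numbers at 2 resolutions stand in the same table. A spot can hold several cells of different types, and all shares are shares of spots.

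The array row and column of each spot were checked against 4 deposited alignment files, each listing 4992 capture spots with a tissue mark. The largest pixel gap to the section's own file was 0.5, and to the file of any other section it was at least 122.9. In sections A, B, C and D, 20, 33, 38 and 29 spots marked as tissue were absent from the spot table and were not used here. No further spot was left out of the main values. Values of single genes and a proliferation score were not analysed here. The rule for named genes, fixed before the data were examined, was to name every score where a table holds no single genes, so all 6 scores are named and no gene is. A list of cell type marker genes fixed at the same time was not used for the same reason.

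The section was the unit of every comparison (n = 4) and spots were never treated as replicates. For each section the mean over the spots of a region was taken, the difference from all other spots of the same section was formed, and the 4 differences were given as mean ± SD. An exact two-sided sign-flip permutation test over the 16 sign assignments was applied to the 4 differences. Its smallest possible p is 0.125, so no comparison could pass 5 in 100, and the number of sections with the same direction is given in place of a call. Benjamini-Hochberg adjustment was applied within each family, of 16 depth, 48 score and 60 interface comparisons. The sections are serial sections of a block treated as 1 sample, so the p-values and SDs measure only the spread between these sections, which may be technical. Exact binomial intervals (95%) for shares cover counting error only.

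Distances were counted in steps on the hexagonal array, in which an interior spot has 6 neighbours. The interface was planned as dark zone spots with a neighbour in the region named Medulla, and 0 dark zone spots had one. The medulla side was therefore taken as Medulla and GC_Medulla Border together, a choice made after the contacts had been counted. The comparisons of light zone contact, of borders with their parent regions, of dark with light zone, of the medulla side 1 to 4 steps against 10 or more steps from a germinal centre, and of dark zone edge spots, as well as the border contact shares, the counts per germinal centre and the comparison of tissue pieces, were likewise added after first looks at the data. Neighbourhoods were measured per section as the log2 ratio of observed adjacent spot pairs to the mean of 1000 shuffles of the region names. Scores were related to each other by Spearman's rho over the spots of each section, with no p-value from spots.

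Some of the functions were tested on simulated data placed on the real spot positions, with noise independent between spots. The function that formed the reported interface differences was not itself run in this test. A shift of 0.1 planted in dark zone spots touching the medulla side was recovered as 0.0906 ± 0.00994 over the 4 sections, and shuffled region names gave a median absolute log2 pair ratio of 0.05. Alternatives fixed beforehand were a minimum of 1000 UMIs per spot, medians, percentile ranks within the section, a residual on log10 UMIs, leaving out spots at the tissue border, equal weights for regions, 2 steps in place of 1, shuffles without like pairs, Pearson correlation, a partial correlation given UMIs, clusters in place of regions, and leaving out each section. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9.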

Results

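The series addresses where plasma cells form from germinal centre B cells in a lymph node, and its title points to the border between the germinal centre dark zone, where B cells divide, and the medulla, the inner compartment in which plasma cells gather before they leave. Spatial expression was recorded in 4 serial sections (A to D) of draining lymph node taken after immunization, all of 1 group. The spot table held 7271 spots over tissue, with 1650, 1876, 1858 and 1887 in sections A, B, C and D. Total UMIs (unique molecular identifiers, each counting 1 captured transcript) were 14281784 in A, 20518149 in B, 8057474 in C and 8016778 in D, so the deepest section had 2.56 times the total of the shallowest. Median UMIs per spot were 7726.5, 10528, 3677.5 and 3836. In every section the spots formed 2 separate pieces of tissue, and whether these are lobes or separate nodes is not given in the sources used here. The pieces are called upper and lower by their mean array row within the section. That each name marks the same tissue in all 4 sections was assumed.

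Of the 8 regions named by the authors, Medulla was the largest with 29.3% ± 2.83 of spots (SD, n = 4), from 25.5% (exact 95% binomial interval 23.6 to 27.6%) in section B to 32.2% (30.1 to 34.4%) in section D, followed by T zone with 25.3% ± 0.868 and B zone with 17.8% ± 1.40. The germinal centres took 7.41% ± 0.736 as DZ and 5.68% ± 0.499 as LZ. Around them lay GC_B Border with 9.18% ± 0.605, GC_Medulla Border with 3.19% ± 0.997 and GC_T Border with 2.17% ± 0.458. GC_Medulla Border ranged from 31 spots in section A, a share of 1.88% (exact 95% binomial interval 1.28 to 2.66%), to 81 spots in section D, a share of 4.29% (3.42 to 5.31%).

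The borders followed position on the array. All 1060 spots of the 3 border regions were 1 step from a DZ or LZ spot, and 0 of the 5258 other spots outside germinal centres were. All 953 DZ and LZ spots fell in a cluster of their own at the finer clustering resolution. Of the 2365 spots of Medulla and GC_Medulla Border, 2361 shared another cluster, so expression clusters did not separate the border from the medulla behind it.

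**Figure D1:**
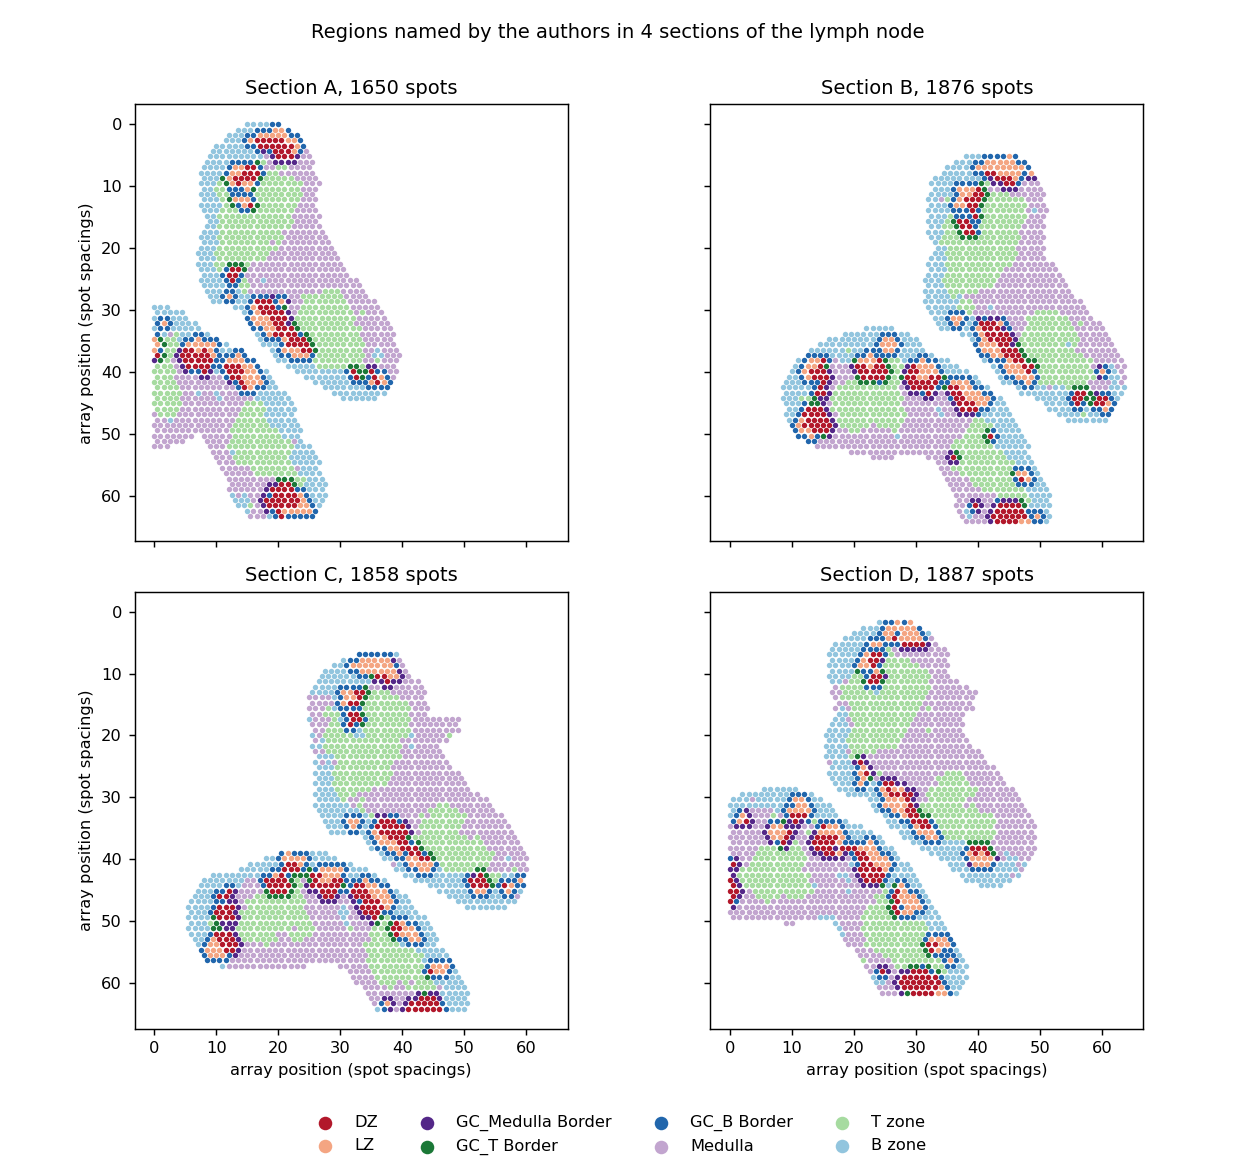
Position of the 7271 spots on the capture array in sections A to D, with both axes in spot spacings and colour giving the region named by the authors. Each section shows 2 separate pieces of tissue, and GC_Medulla Border spots lie mostly beside DZ.

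Germinal centre spots had the most UMIs and medulla spots the fewest. LZ spots averaged 11476 ± 4927 UMIs and DZ spots 10446 ± 4296, against 4305 ± 2458 in Medulla and 4686 ± 2598 in GC_Medulla Border (SD over 4 sections that differ in depth). Within sections, DZ exceeded the other spots by 3676 ± 1406 UMIs and LZ by 4693 ± 1989, each in 4 of 4 sections, and the Medulla difference was -3844 ± 1885 UMIs, below 0 in 4 of 4. B zone and GC_B Border lay above the other spots by 1985 ± 684 and 1723 ± 782 UMIs. Of 16 comparisons of UMIs and genes by region, 14 had 1 direction in all sections (smallest exact sign-flip p = 0.13, adjusted p 0.143). T zone differed by -462.3 ± 377 UMIs as means, and by 82.3 with medians over spots.

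The germinal centre score was higher in DZ and LZ, which formed an expression cluster of their own, than in all other regions. Mo_GC_vs_Mem averaged 0.265 ± 0.0121 in DZ and 0.259 ± 0.0110 in LZ, then 0.197 ± 0.00559 in GC_B Border, 0.183 ± 0.00880 in B zone, 0.167 ± 0.0105 in GC_T Border, 0.148 ± 0.0143 in T zone, 0.144 ± 0.0177 in GC_Medulla Border and 0.123 ± 0.0186 in Medulla. DZ exceeded the other spots by 0.106 ± 0.0101 and LZ by 0.0982 ± 0.00727, in 4 of 4 sections each. DZ and LZ differed by 0.00551 ± 0.00477, with DZ higher in 4 of 4 sections, but on percentile ranks the mean difference was -0.843 points with DZ higher in 1 section. The score ran with depth, with a rho of 0.787 ± 0.101 against UMIs over all spots. After a linear fit on log10 UMIs, the DZ difference was 0.0730 and the LZ difference 0.0588, and the B zone difference of 0.0202 ± 0.00687 became -0.00364.

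The plasma cell marker score had the opposite layout, highest in GC_Medulla Border and Medulla and lowest in the germinal centres. The score pc_markers averaged 0.308 ± 0.0608 in GC_Medulla Border and 0.279 ± 0.0631 in Medulla, then 0.228 ± 0.0188 in GC_T Border, 0.204 ± 0.0236 in T zone, 0.164 ± 0.0212 in B zone, 0.161 ± 0.0171 in GC_B Border, 0.153 ± 0.0177 in DZ and 0.115 ± 0.0151 in LZ. Against the other spots of the section, GC_Medulla Border was higher by 0.102 ± 0.0338 and Medulla by 0.0976 ± 0.0418, while DZ differed by -0.0601 ± 0.0179 and LZ by -0.0990 ± 0.0166, each with the same direction in 4 of 4 sections. The 2 deeper sections, A and B, had the higher Medulla values, 0.299 and 0.359, against 0.227 and 0.230 in C and D. Within the upper tissue piece the GC_Medulla Border difference was 0.0552, above 0 in 4 of 4 sections. The order of GC_Medulla Border over Medulla did not hold there, with a difference of -0.000322, above 0 in 1 of 4 sections, nor against Medulla spots 2 steps from a germinal centre, with 0.00916 in 2 of 4.

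**Figure D2:**
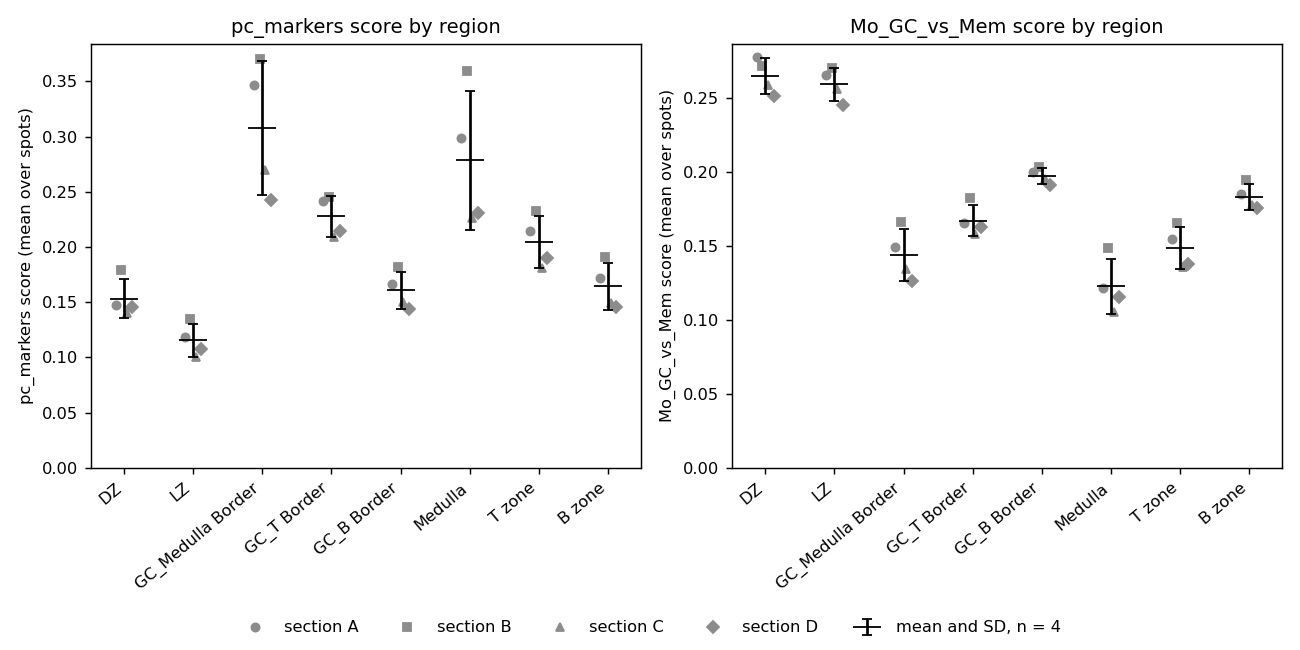
Mean pc_markers score (left) and Mo_GC_vs_Mem score (right) over the spots of each region, with 1 grey point per section and black lines for mean and SD over 4 sections; axes are in score units. The plasma cell marker score is highest in GC_Medulla Border (0.308) and Medulla (0.279) and lowest in LZ (0.115), and the germinal centre score is highest in DZ (0.265) and lowest in Medulla (0.123).

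The 4 scores ending in SC shared a medullary pattern and were lowest in germinal centres. In Medulla, Mo_Nr4a1_SC averaged 0.0197 ± 0.00793, Mo_Inmt_SC -0.00197 ± 0.00331, Mo_Nr4a1Inmt_SC -0.0109 ± 0.00513 and Mo_CD34_SC 0.00969 ± 0.00644. The differences from the other spots were 0.0331 ± 0.00878, 0.0431 ± 0.00678, 0.0369 ± 0.00699 and 0.0362 ± 0.00588 in the same order, each above 0 in 4 of 4 sections. After a linear fit on log10 UMIs, which were lowest in Medulla, the 4 differences were 0.0236, 0.0270, 0.0240 and 0.0230. In DZ the same 4 differences were -0.0205 ± 0.00465, -0.0362 ± 0.00386, -0.0350 ± 0.00393 and -0.0401 ± 0.00366, each below 0 in 4 of 4. GC_Medulla Border lay between these levels, with values of 0.00743 ± 0.00694, -0.0200 ± 0.00182, -0.0302 ± 0.00196 and -0.00712 ± 0.00384. Mo_CD34_SC was the only 1 of the 4 with T zone above the other spots, by 0.00264 ± 0.00100 in 4 of 4 sections, and within the upper tissue piece that difference was -0.00114. Over the 6 scores, 44 of 48 differences by region had 1 direction in all sections, with a smallest exact sign-flip p = 0.13 and a smallest adjusted p of 0.136. As the regions largely followed expression clusters, this count is partly built in.

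At the interface, dark zone spots touching the medulla side had a higher plasma cell marker score and a lower germinal centre score than the rest of the dark zone. The 173 DZ contact spots averaged 0.203 ± 0.0342 in pc_markers against 0.131 ± 0.0113 in other DZ spots, a difference of 0.0721 ± 0.0273 (n = 4), higher in 4 of 4 sections (exact sign-flip p = 0.13, adjusted p 0.147). Their Mo_GC_vs_Mem score was 0.236 ± 0.0111 against 0.278 ± 0.00927, a difference of -0.0423 ± 0.00849, below 0 in 4 of 4, and -0.0166 after a linear fit on log10 UMIs. Mo_Nr4a1_SC, Mo_Inmt_SC, Mo_Nr4a1Inmt_SC and Mo_CD34_SC were higher in the contact spots by 0.0128 ± 0.00355, 0.0190 ± 0.00418, 0.0144 ± 0.00362 and 0.0213 ± 0.00308, each in 4 of 4 sections. All medullary scores were thus higher there and not the plasma cell marker score alone. The same directions appeared away from the medulla side. DZ spots touching only the T or B side differed from interior DZ spots by -0.0380 in Mo_GC_vs_Mem and 0.0617 in pc_markers. The SC scores differed by 0.00792, 0.0126, 0.00848 and 0.0160 in the order above. Each held in 4 of 4 sections, so the direction of these shifts was not particular to medulla contact. The sizes were not tested against each other, as the reference spots differ. Contact spots also held fewer UMIs, 7761 ± 3316 against 11206 ± 4813 in DZ spots 2 steps from the medulla side. With contact widened to 2 steps the pc_markers difference was 0.0300 and the Mo_GC_vs_Mem difference -0.0196.

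In the dark zone, pc_markers was higher in spots touching the medulla side than in spots 2 or 3 steps away. By steps from the medulla side, DZ spots averaged 0.203 ± 0.0342 at 1 step, 0.128 ± 0.0119 at 2 steps and 0.127 ± 0.00871 at 3 steps. All DZ spots at 2 or more steps, which include those beyond 3 steps, averaged 0.131 ± 0.0113. Medulla-side spots averaged 0.316 ± 0.0593 at 1 step from DZ, 0.303 ± 0.0667 at 2, 0.296 ± 0.0519 at 3 and 0.252 ± 0.0627 at 10 or more. Taken within tissue pieces, medulla-side spots 1 to 4 steps from a germinal centre differed from those 10 or more steps away by 0.0295 ± 0.0299, and by -0.0119 in section D. The contact spots on the medulla side exceeded the rest of the medulla side by 0.0378 ± 0.0219 in 4 of 4 sections, and GC_Medulla Border exceeded Medulla by 0.0289 ± 0.0198 in 4 of 4. Neither held in each tissue piece. Within the upper piece GC_Medulla Border minus Medulla was -0.000322 and above 0 in 1 of 4 sections, within the lower piece it was 0.0182 and above 0 in 3 of 4, and against Medulla spots 2 steps from a germinal centre alone it was 0.00916, above 0 in 2 of 4. For the contact spots on the medulla side the difference was 0.0112 in the upper piece (2 of 4 sections) and 0.0231 in the lower piece (3 of 4). The difference between DZ contact spots and other DZ spots was above 0 in 4 of 4 sections in both pieces, at 0.0499 ± 0.0285 in the upper and 0.0885 ± 0.0365 in the lower.

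**Figure D3:**
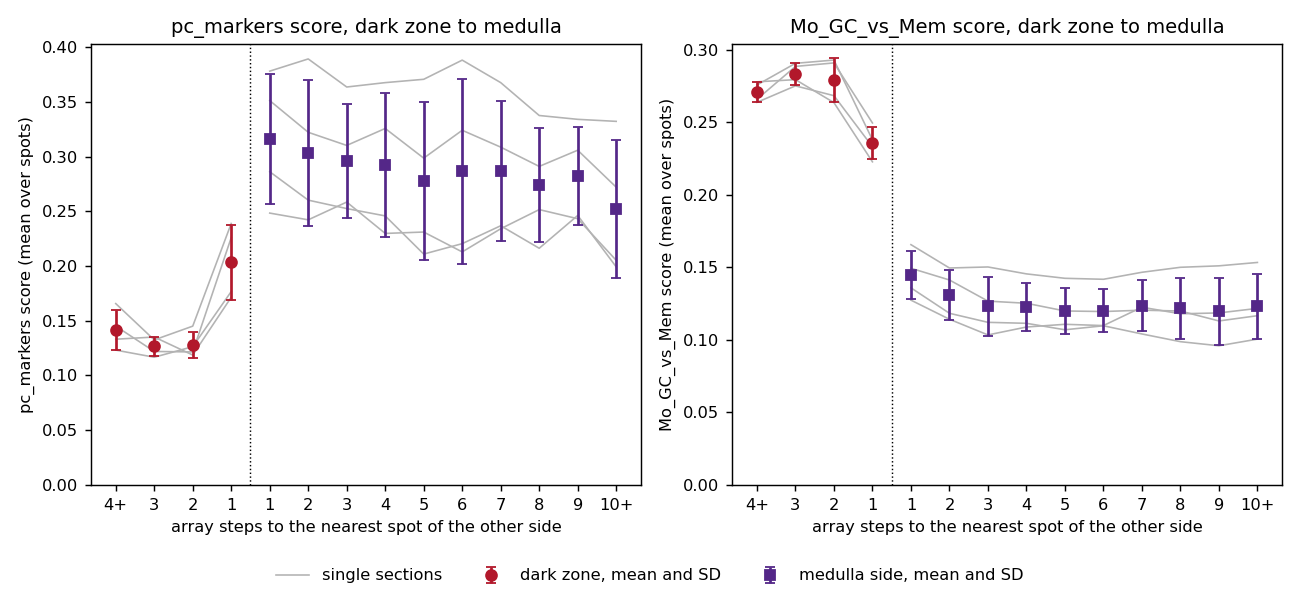
Mean pc_markers score (left) and Mo_GC_vs_Mem score (right) in score units against the number of array steps to the nearest spot of the other side, with dark zone spots left of the dotted line and medulla-side spots right of it; points and bars are mean and SD over 4 sections and grey lines single sections. In the dark zone the plasma cell marker score is 0.203 at 1 step and 0.128 at 2 steps, and the germinal centre score is 0.236 at 1 step and 0.279 at 2 steps.

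The plasma cell marker score was also compared at the light zone and at the other borders, and a difference between borders was not tested. DZ spots exceeded LZ spots in pc_markers by 0.0378 ± 0.00636 in 4 of 4 sections. LZ spots touching the medulla side were few, 27 in all and 2 in the section with fewest, and differed from other LZ spots by 0.00843 ± 0.0205, higher in 2 of 4 sections. Without section B that value was -0.00142. GC_T Border exceeded T zone by 0.0234 ± 0.00715 in 4 of 4 sections, and GC_B Border differed from B zone by -0.00364 ± 0.00435, higher in 1 of 4. Along the medulla side, spots 1 to 4 steps from a germinal centre averaged 0.301 ± 0.0606 and spots 10 or more steps away 0.248 ± 0.0599, a difference of 0.0535 ± 0.00956 in 4 of 4 sections. That difference was 0.0411 ± 0.0343 within the upper tissue piece, above 0 in 4 of 4 sections, and 0.0178 ± 0.0520 within the lower, above 0 in 3 of 4. Mo_Nr4a1_SC, Mo_Inmt_SC, Mo_Nr4a1Inmt_SC and Mo_CD34_SC went the other way, with differences of -0.00711 ± 0.00339, -0.0132 ± 0.00648, -0.0157 ± 0.00426 and -0.0180 ± 0.00798, below 0 in 4 of 4 sections. The difference between these directions was not tested. Of the 60 interface comparisons computed, 51 had 1 direction in all sections.

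Light zones bordered the B cell follicle almost alone, while dark zones bordered the follicle, the medulla and the T zone. Of the contacts that DZ spots made with border spots, 35.5% ± 9.07 were with GC_Medulla Border, 23.1% ± 4.39 with GC_T Border and 41.4% ± 9.58 with GC_B Border. For LZ spots the same shares were 5.10% ± 4.36, 2.64% ± 2.20 and 92.3% ± 4.10. The GC_Medulla Border share was higher in DZ than in LZ by 30.4 ± 5.77 percentage points in 4 of 4 sections (exact sign-flip p = 0.13, n = 4). Against shuffled region names, DZ was adjacent to GC_Medulla Border with a log2 ratio of 1.75 ± 0.07. The ratio was 1.66 ± 0.27 for DZ with GC_T Border and 0.40 ± 0.22 for DZ with GC_B Border. Each of these was above 0 in 4 of 4 sections. LZ was adjacent to GC_B Border with 1.89 ± 0.08, to GC_Medulla Border with -1.18 ± 0.97 and to GC_T Border with -1.48 ± 1.45, the last below 0 in 3 of 4 sections. Every border spot lay 1 step from a DZ or LZ spot, and shuffling over the whole section ignores this. Ratios above 0 between a zone and a border are therefore partly built in, and the comparison of DZ with LZ is less bound by it. The DZ minus LZ difference in log2 ratio was 2.94 ± 0.97 for GC_Medulla Border, 3.13 ± 1.60 for GC_T Border and -1.49 ± 0.19 for GC_B Border, each with 1 direction in 4 of 4 sections. Large regions were adjacent to themselves more often than under shuffling, with log2 ratios of 1.53 ± 0.14 for Medulla, 1.79 ± 0.05 for T zone and 1.95 ± 0.07 for B zone. When like pairs were left out of the expected value, LZ with GC_Medulla Border became 0.25.

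**Figure D4:**
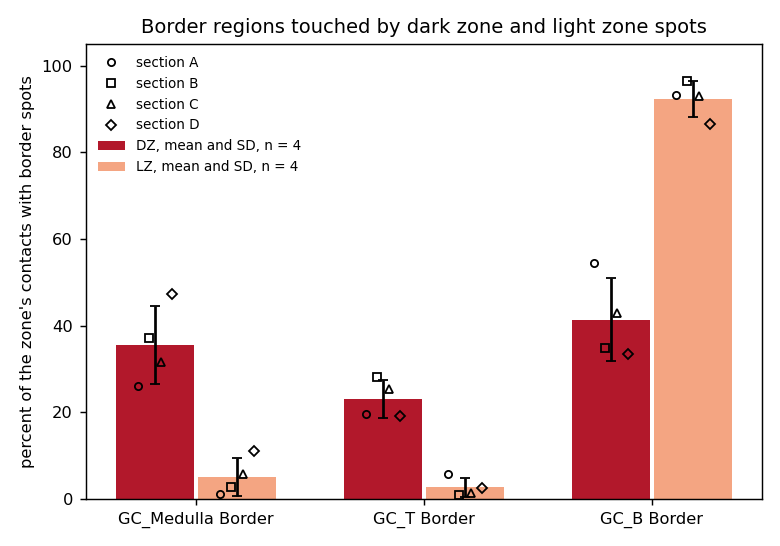
Percent of the contacts of DZ and LZ spots with border spots that fall on each border region, as bars for the mean and SD over 4 sections and 1 symbol per section. GC_Medulla Border takes 35.5% of DZ and 5.10% of LZ contacts, and GC_B Border takes 41.4% and 92.3%.

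Over all spots, spots with a high germinal centre score had a low plasma cell marker score. Spearman's rho between pc_markers and Mo_GC_vs_Mem was -0.514 ± 0.143 (4 of 4 sections below 0), and inside DZ it was -0.710 ± 0.0945. It was -0.316 ± 0.143 in LZ and -0.267 ± 0.144 in GC_B Border, below 0 in 4 of 4 sections each. In the other 5 regions it had no shared direction, with 0.00322 ± 0.239 in GC_Medulla Border, -0.0527 ± 0.251 in Medulla, 0.135 ± 0.154 in T zone, -0.0993 ± 0.189 in B zone and -0.0957 ± 0.132 in GC_T Border. The score pc_markers correlated with Mo_CD34_SC at 0.594 ± 0.106, with Mo_Inmt_SC at 0.476 ± 0.12, with Mo_Nr4a1Inmt_SC at 0.446 ± 0.119 and with Mo_Nr4a1_SC at 0.390 ± 0.118. Inside DZ the correlation with Mo_CD34_SC was 0.732 ± 0.0514, and inside LZ it was 0.280 ± 0.192. Among the 4 SC scores, the highest correlation was 0.780 ± 0.0617, between Mo_Inmt_SC and Mo_Nr4a1Inmt_SC, and shared genes between the lists could not be examined because their members are not given in the sources used here.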

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

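The tests on germinal centre RNA, on tissue pieces, on medulla RNA mixed into a spot and on how zones were placed and named were chosen after the results they concern had been seen.

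Of 134 results, 3 had a section far from the other 3, and chance alone marks about 1 in 20 groups of this size. For Mo_GC_vs_Mem in GC_Medulla Border against other spots, section D stood at -0.0303, with the others between -0.0215 and -0.0200. For Mo_Nr4a1Inmt_SC in GC_Medulla Border, section B stood at 0.0113, with the others between 0.00566 and 0.00606. For Mo_CD34_SC in GC_B Border, section A stood at -0.0177, with the others between -0.0212 and -0.0209.

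The higher plasma cell marker score of dark zone spots touching the medulla side was weighed against 3 technical explanations. Lower depth of these spots does not account for it, since the difference was 0.0683 ± 0.0283 after matching on UMI quartiles against 0.0721 ± 0.0273 before. A general edge effect stays open: DZ spots touching only the T or B side exceeded interior DZ spots by 0.0617 ± 0.00740, and contact spots exceeded the interior by 0.104 ± 0.0254. Mixing of medulla RNA into these spots cannot be told apart from local plasma cells. The implied share was taken on a scale from interior DZ spots to GC_Medulla Border spots. Medulla itself was not used as an end of that scale, and another end would give other shares. On this scale pc_markers implied a share of 50.1% ± 5.36. The lowest and highest of the other 5 scores, taken anew in each section, averaged 36.9% ± 5.20 and 49.4% ± 3.80. The pc_markers share lay above the range of its section in 2 of 4 sections and inside it in 2. No biological explanation was tested, as all sections belong to 1 group.

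The higher plasma cell marker score of medulla-side spots near germinal centres was weighed in the same way. Shallow or outer spots far from germinal centres do not account for it, with 0.0530 ± 0.0118 left without them, nor does depth, with 0.0467 ± 0.00493 after matching against 0.0535 ± 0.00956 before. RNA from germinal centres would lower the score, since DZ and LZ spots lay at -0.111 ± 0.0438 relative to far medulla-side spots. A difference between tissue pieces stays open: taken within pieces, the value was 0.0295 ± 0.0299, and in section D it was -0.0119. No biological explanation was tested.

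The dark zone lay nearer the medulla side than the light zone in 31 of 33 germinal centres with at least 3 spots of each zone, counted per section, so that a germinal centre can recur in several sections. They were part of 14, 21, 18 and 17 connected patches in sections A to D, and the mean distance was 2.36 ± 0.159 steps for DZ and 3.85 ± 0.281 for LZ. The share with the dark zone nearer, 94.4% ± 6.57 per section, restates this pattern and so tests no explanation, and random placement was not tested apart from it. Naming by distance alone would order nearly all spot pairs, and the share with the DZ spot nearer was 85.7% ± 1.88 when each tied pair was counted as 0.5. Ties in whole steps made up 166 of 1380, 154 of 1392, 148 of 1123 and 213 of 1497 pairs in sections A to D. Counting them as 0.5 lowers the share, so it cannot decide on naming by distance. How the zones were named is not given in the sources used here, so a rule that used position beside expression stays open and no biological explanation was tested.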

How the results depend on the processing

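The values for single tissue pieces, for sections A and B alone, for Medulla without its border and for spots 2 steps from a germinal centre were chosen after the data had been seen. Of 1374 alternative values for 134 results, 1169 kept direction and agreement between sections and, where the scale was the same, lay within 1 SD. Most of the 48 score differences by region did not meet this with a residual on log10 UMIs, nor with regions weighted equally. In 4 of the 48 under each of these 2 settings the direction was turned. In 14 values a direction that all 4 sections shared was turned. Sign changes of results without such a shared direction are not among these 14. For example, the T zone difference in genes ran from -33.5 to 73.2 when single sections were left out. Leaving out each section in turn gave 0.0629 to 0.0814 for the pc_markers difference of DZ contact spots. Such means cannot leave 1 SD with 4 sections, nor turn a direction that all 4 share, so they test little. The 1374 values include these means for each of the 134 results. Nearly all of them are among the 1169, so that count overstates how stable the results are. The cause of the changes below was not tested.

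With a residual on log10 UMIs, Mo_GC_vs_Mem against other spots was 0.0730 in DZ, 0.0588 in LZ, 0.00173 in GC_Medulla Border and -0.00364 in B zone, and -0.0166 for DZ contact spots. Medulla was at 0.0236 for Mo_Nr4a1_SC, 0.0270 for Mo_Inmt_SC, 0.0240 for Mo_Nr4a1Inmt_SC and 0.0230 for Mo_CD34_SC, and B zone at 0.00253 for Mo_Inmt_SC and 0.00428 for Mo_Nr4a1Inmt_SC. With medians, Mo_GC_vs_Mem was 0.119 in DZ and -0.0518 for DZ contact spots, pc_markers -0.0822 in LZ, Mo_Nr4a1Inmt_SC 0.000383 in B zone, and T zone UMIs 82.3. With regions weighted equally, Mo_GC_vs_Mem was 0.0902 in DZ, 0.0839 in LZ and -0.00303 in B zone, where Mo_Inmt_SC was 0.00300, Mo_Nr4a1Inmt_SC 0.00596 and Mo_CD34_SC 0.000344. On percentile ranks, DZ minus LZ in Mo_GC_vs_Mem was -0.843.

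With contact within 2 steps, DZ contact spots were at -0.0196 in Mo_GC_vs_Mem and 0.0300 in pc_markers, and with Medulla without its border the medulla-side contact spots were at 0.00915 in Mo_GC_vs_Mem. In the upper tissue piece, pc_markers was 0.0552 for GC_Medulla Border against other spots, 0.0112 for medulla-side contact spots and -0.000322 for GC_Medulla Border minus Medulla, and Mo_CD34_SC in T zone was -0.00114. In the lower piece the same pc_markers values were 0.0231 for contact spots and 0.0182 for border minus Medulla, and against spots 2 steps away the latter was 0.00916. The log2 adjacency of LZ and GC_Medulla Border was 0.25 without like pairs, and the DZ minus LZ value for GC_B Border was -1.04 within 2 steps.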

Other observations

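The comparison of tissue pieces and of mitochondrial and ribosomal shares between neighbouring regions was chosen after the data had been seen.

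Mitochondrial and ribosomal shares of counts also followed the regions. The mitochondrial share was highest in Medulla, 5.58% ± 0.592, and lowest in DZ, 3.26% ± 0.552, against 4.47% ± 0.395 in LZ. DZ minus LZ was -1.21 ± 0.304 percentage points for mitochondrial and -1.95 ± 0.337 for ribosomal genes, below 0 in 4 of 4 sections. Each border had a lower mitochondrial share than its parent region in 4 of 4 sections, with differences of -1.72 ± 0.465 points at GC_Medulla Border, -0.345 ± 0.133 at GC_T Border and -0.800 ± 0.352 at GC_B Border. T zone and B zone had the highest ribosomal shares, 23.7% ± 2.25 and 23.8% ± 2.01.

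The 2 tissue pieces of a section were unlike in plasma cell marker score. The lower piece had a Medulla pc_markers score of 0.311 ± 0.0589 and the upper piece 0.257 ± 0.0642, a difference of 0.0547 ± 0.0158 in 4 of 4 sections (exact sign-flip p = 0.13, n = 4). Of the contacts of DZ spots with borders, 43.3% ± 7.47 were with GC_Medulla Border in the lower piece and 25.1% ± 9.07 in the upper, higher in the lower in 4 of 4 sections. The germinal centre score of DZ was 0.266 ± 0.0109 in the lower and 0.263 ± 0.0171 in the upper piece.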
